A study of Canis lupus familiaris with 14 samples.

How the data were processed

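Total RNA from gingival margin tissue of companion dogs with periodontal disease was sequenced as 14 libraries. The labels grade the disease as Moderate for 10 libraries and as Severe for 4. Per the labels' protocols, tissue was homogenized in TRIzol, RNA was purified on columns with DNase treatment, ribosomal RNA was depleted with a human, mouse and rat reagent, and directional libraries were prepared.

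The authors deposited a table of raw counts, 1 whole number per Ensembl dog gene and library, for 30951 genes. The submitters' processing notes name the aligner STAR and the genome build canFam3. The counting tool, its strand setting, the annotation release and the STAR version are not given in the sources used here. It is therefore not known how reads from overlapping genes, antisense genes and near-identical copies were counted. Each column was matched to its library by the library name in the labels. A second deposited table holds 7 columns of counts named as mild disease. Their names match none of the 14 libraries and the series text says that other deposited accessions were reused, so these 7 columns were not used here and no comparison with mild disease was made.

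The files do not pair Ensembl identifiers with gene symbols. The table of RefSeq genes used here (assembly UU_Cfam_GSD_1.0) has no entry in its Ensembl column, and 0 of the 30951 identifiers could be matched to a symbol. The 37 lists of pathway and cell type markers that had been fixed before the data were examined, and the 6 planned relations between list scores, could therefore not be computed. Coordinates are not given for the same reason.

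Library totals ran from 14565934 to 16421547 counts. No row lacked a gene identifier, and 5996 genes had no count in any library. Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 14858 genes holding 99.9% of all counts. Libraries were scaled by the trimmed mean of M-values (TMM). CPM values, each gene's count relative to the scaled library total, were computed from these totals, and log2 CPM with a prior count of 2. The numbers of genes at 1 CPM or more were instead counted over all 30951 genes with unscaled library totals. Severe and Moderate libraries were compared with edgeR's quasi-likelihood test, two-sided, on all 14 libraries with no covariate, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05. A secondary comparison set libraries whose description carries the code FS (6) against those coded MC (7) or M (1), with disease state in the model. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic, and 95% intervals used the test's degrees of freedom; both are approximate. Nothing in the labels states that each library is a separate dog, although library numbers all differ, so p-values measure the spread between these libraries.

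The design, the tests and most alternatives were fixed before the data were examined. The rule for naming genes called for genes with a symbol. Since no symbol was available, the 2 identifiers with the smallest unadjusted p in each direction were named for disease state. They were taken among genes with a mean of at least 1 CPM in either grade. For the codes, 2 of the 5 identifiers with the smallest p were named, with no such floor. The rule's highest-expressed genes were described by rank only. The principal components (over log2 CPM of the 14858 genes) and the exact permutation tests on whole libraries (pseudo-F, the ratio of between-group to within-group squared distances, over all 1001 splits into 4 and 10 or all 3003 into 6 and 8) were chosen after the data were seen.

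The gene test was tested on simulated counts drawn from the observed means, dispersions and library sizes of the 14858 genes, with 200 changed genes in each of 3 simulated sets. For Severe against Moderate, 29.4% of genes changed 2-fold, 70.6% of those changed 4-fold and 88.9% of those changed 8-fold were called. For the FS comparison the shares were 29.4%, 77.6% and 87.4%. Simulated genes varied independently, unlike genes in tissue.

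Alternatives were DESeq2 size factors and upper-quartile factors in place of TMM, no low-count filter, a filter of 1 CPM in 4 libraries, a robust dispersion fit, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with sample quality weights, a minimum absolute log2 fold change of 1, the description code or 1 surrogate variable (sva 3.50.0) as a covariate, a block on replicate number, and leaving out each library in turn. Every pair of libraries differed by more than sampling noise: the chi-square statistic per degree of freedom, over genes with 20 or more counts in the pair, was 34.9 or higher, so no 2 libraries agreed within counting noise. This does not show that they came from separate dogs, and the 14 were counted as separate samples on their labels alone. No batch or date is given in the labels. The labels list 9 breed entries for the 14 libraries, 5 of them with 1 library each. Breed as a covariate was added after the data were seen; it leaves 4 residual degrees of freedom for disease state and 3 for the code, and compares the grades only within the 3 breed entries that have both.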

Results

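Gene expression was profiled by RNA sequencing in gingival margin tissue from companion dogs with periodontal disease of differing severity, a bacterially driven inflammation of the tissues that hold the teeth. The question of the study was which genes differ with the degree of disease. Moderate disease was represented by 10 libraries and severe disease by 4. Sequencing depth was even: totals averaged 15563196 counts ± 519795 (SD, n = 10) in Moderate and 15476237 ± 786235 (SD, n = 4) in Severe libraries. The number of genes at 1 CPM or more was 13351 ± 390.2 (SD, n = 10) in Moderate and 13380 ± 230.2 (SD, n = 4) in Severe tissue. Genes are given by the Ensembl identifiers of the count table, because symbols could not be assigned, and nothing can be said here about which pathways or cell types they belong to.

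The gene with the highest mean abundance took 5.18% ± 1.55 (SD, n = 10) of counts in Moderate and 4.83% ± 0.178 (SD, n = 4) in Severe libraries. The 5 genes with the highest mean abundance over all libraries together took 10.3% ± 2.89 (SD, n = 10) and 9.25% ± 1.25 (SD, n = 4). The log2 CPM values of 2 libraries of the same grade correlated across genes with an r between 0.80 and 0.96, with a median of 0.93 (51 pairs), against a median of 0.94 between the grades (40 pairs), where genes are not independent replicates. The first principal component held 39.5% of the variance between libraries and the second held 12.9%.

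Severe and Moderate libraries overlapped on the first component. Moderate libraries lay between -78.5 and 102 (mean 8.15 ± 61.4 SD, n = 10), and Severe libraries lay between -58.7 and 26.6 (mean -20.4 ± 35.2 SD, n = 4). The difference of -28.5 was within the spread between libraries (exact permutation test, two-sided, p = 0.404; adjusted p = 0.640 over a family of 6 tests on whole libraries). Over all tested genes the pseudo-F of disease state was 0.985 (exact permutation test over 1001 splits, one-sided for larger values, p = 0.384; adjusted p = 0.640). The root mean squared distance between libraries was 105 within Severe and 131 within Moderate disease, a difference of -26.2 that was not larger than chance splits gave (exact permutation test, two-sided, p = 0.171; adjusted p = 0.640). The numbers of genes at 1 CPM differed by 28.6 on average (exact permutation test, two-sided, p = 0.897; adjusted p = 0.897).

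**Figure D1:**
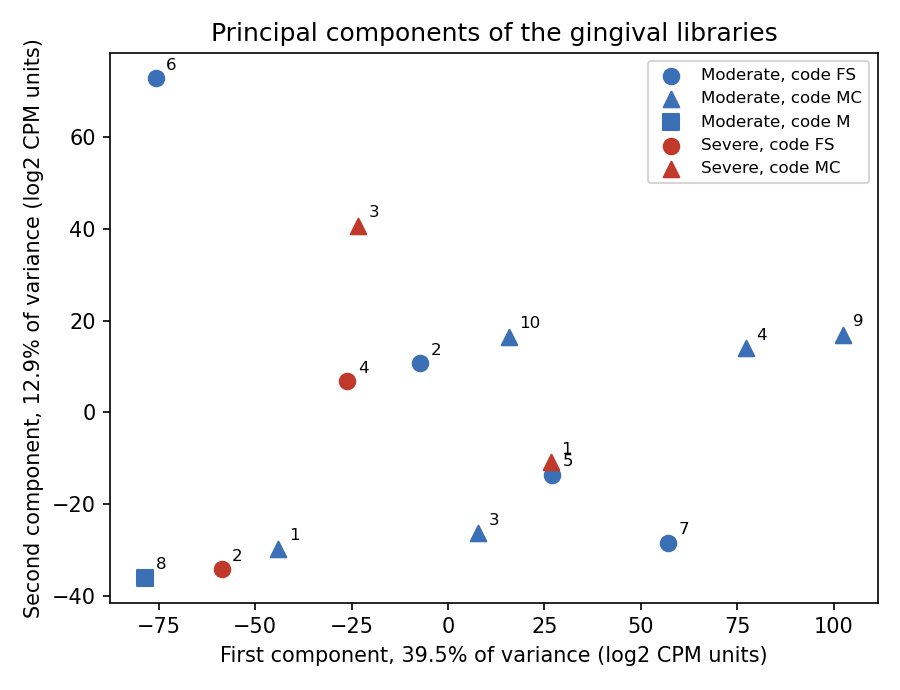
First (horizontal axis) and second (vertical axis) principal components of log2 CPM over 14858 genes, in log2 CPM units, with 1 point per library, coloured by disease grade, shaped by the code in the description and numbered by replicate. The 4 Severe libraries lie between -58.7 and 26.6 on the first component, inside the range of the Moderate libraries, and Moderate replicate 6 stands apart on the second component at 72.9.

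Gene by gene, no gene differed between Severe and Moderate tissue at the threshold. Of 14858 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.668. At an unadjusted p under 0.05 there were 1111 genes, of which 466 had higher and 645 had lower values in Severe libraries, where 743 genes would be expected by chance. Leaving out 1 library in turn gave from 604 (without Severe replicate 3) to 1533 (without Moderate replicate 6). That count was 678 and 733 without Severe replicates 2 and 4, and 1422 without Moderate replicate 2. Leaving out Severe replicate 1 gave 1184, and leaving out Moderate replicate 4 gave 778. The DESeq2 Wald test and limma-voom with quality weights also called 0 genes. DESeq2, which was run without the low-count filter, put 1605 genes at an unadjusted p under 0.05, where edgeR without that filter put 1510. On the filtered genes limma-voom put 2647 there, of which 42.2% were lower in Severe, against 58.1% with edgeR. The balance of higher and lower values therefore depended on the method.

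The identifiers with the smallest unadjusted p, among genes with a mean of at least 1 CPM in either grade, are given as values, since none passed the test. ENSCAFG00000002552 had 30.0 CPM ± 2.58 (SD, n = 4) in Severe and 21.7 CPM ± 2.26 (SD, n = 10) in Moderate libraries, a log2 fold change of 0.47 ± 0.12 (SE). ENSCAFG00000018024 had 119 CPM ± 9.90 (SD, n = 4) against 83.4 CPM ± 12.8 (SD, n = 10), a log2 fold change of 0.51 ± 0.13 (SE). In the other direction, ENSCAFG00000000437 had 66.3 CPM ± 7.50 (SD, n = 4) in Severe against 116 CPM ± 25.7 (SD, n = 10) in Moderate libraries, a log2 fold change of -0.80 ± 0.18 (SE). ENSCAFG00000005203 had 6.03 CPM ± 0.858 (SD, n = 4) against 13.2 CPM ± 3.93 (SD, n = 10), a log2 fold change of -1.12 ± 0.26 (SE). All 4 of these had an adjusted p of 0.668 in edgeR's quasi-likelihood test. The DESeq2 Wald test gave them an adjusted p of 0.0931 to 0.156, and limma-voom with quality weights gave 0.101 to 0.120. Over the 26 alternatives that gave them a fold change, the adjusted p reached 0.965 for each (edgeR without Severe replicate 2). In each of them the 4 Severe libraries lay outside the range of the 10 Moderate libraries. Such separation was seen for 70 genes (0.471% of those tested, 42 higher and 28 lower in Severe), where a gene has a 0.200% chance of it, and 90 of all 1001 splits of the libraries into 4 and 10 gave as many (exact share 0.0899).

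**Figure D2:**
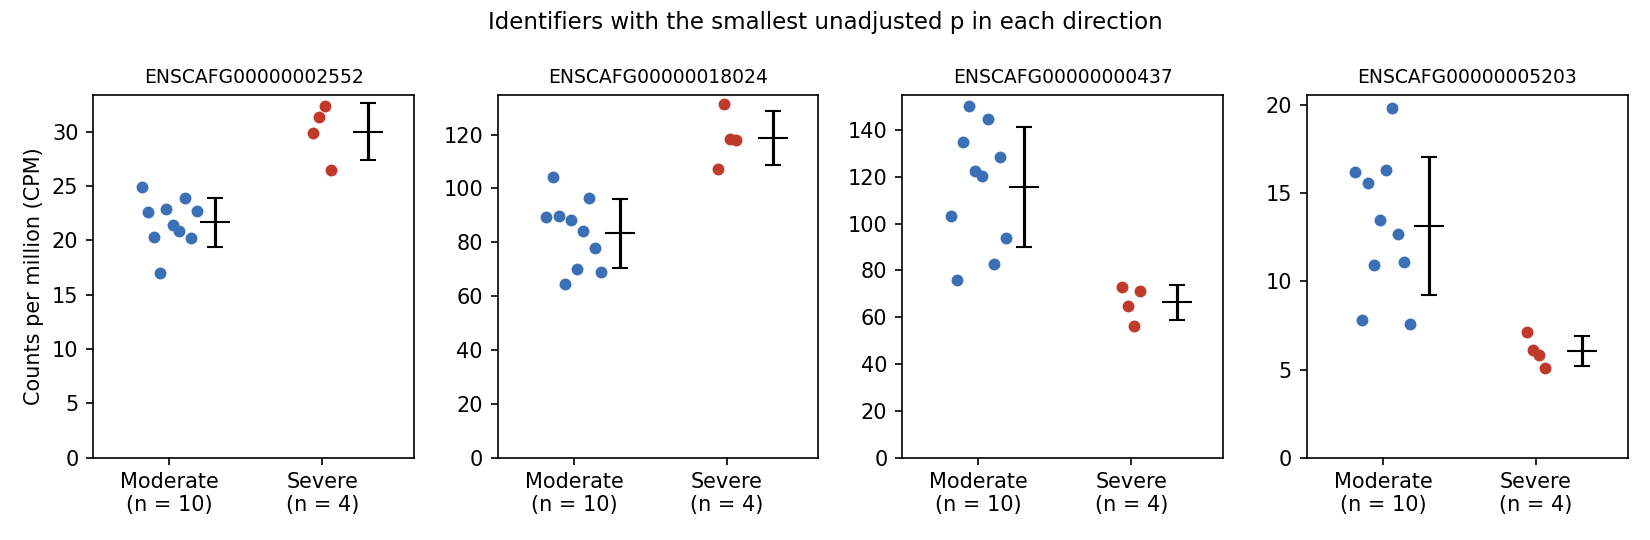
CPM (vertical axes, each starting at 0) of the 2 identifiers with the smallest unadjusted p in each direction, with 1 point per library in the Moderate (n = 10) and Severe (n = 4) groups and bars for the mean ± SD. The identifiers were taken among genes with a mean of at least 1 CPM in either grade. The 4 Severe libraries lie above all Moderate libraries for ENSCAFG00000002552 and ENSCAFG00000018024 and below them for ENSCAFG00000000437 and ENSCAFG00000005203, and none of the 4 passed the adjusted threshold.

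The size of change left open for each gene was gauged by its approximate 95% interval. These intervals were not adjusted for the number of genes and rest on 4 Severe libraries. Genes are also not independent, so the counts below are no joint bound on the changes. The median standard error of the log2 fold change was 0.27. For 8974 genes (60.4%) the approximate 95% interval lay within a 2-fold change in either direction, and for 13168 genes (88.6%) it lay within a 4-fold change. For the remaining genes these intervals do not exclude larger differences between Severe and Moderate tissue.

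Libraries were also compared by the code in their description, FS against MC or M, as a label check with disease state in the model. The labels do not say what the codes mean. The gene XIST, planned to be read in each library as part of this check, could not be identified without symbols. Again 0 of 14858 genes passed edgeR's quasi-likelihood test, with a smallest adjusted p of 0.791, and 324 genes had an unadjusted p under 0.05 (526 without Moderate replicate 7), fewer than the 743 expected by chance. The 5 genes with the smallest p all had higher values in FS libraries, by 0.47 to 0.62 on the log2 scale, and the next 2 had lower values, with log2 fold changes of -3.42 and -0.50 and an adjusted p of 0.999 for each. The -3.42 belonged to a gene near the floor, with a mean of 0.0747 CPM in FS and 0.919 CPM in the other libraries. ENSCAFG00000014207 had 270 CPM ± 36.2 (SD, n = 6) in FS and 174 CPM ± 19.2 (SD, n = 8) in the other libraries, a log2 fold change of 0.62 ± 0.11 (SE), and its FS libraries lay above all others. Such separation was seen for 4 genes (0.0269% of those tested, 2 higher and 2 lower in FS), against a mean of 9.90 (0.0666%) expected by chance. Genes are not independent, and how many splits give as few was not computed. ENSCAFG00000014589 had 81.4 CPM ± 12.2 (SD, n = 6) against 53.1 CPM ± 7.38 (SD, n = 8), a log2 fold change of 0.60 ± 0.11 (SE), with overlapping groups. With the DESeq2 Wald test, in place of edgeR, 5 genes passed, 4 of them higher in FS, and both named identifiers were among them with an adjusted p of 7.5e-04 for ENSCAFG00000014207 and 0.0071 for ENSCAFG00000014589. Over all 22 alternatives that gave these 2 identifiers a value, the adjusted p ranged from these DESeq2 values to 1 for each. Without Moderate replicate 6, edgeR called 2 genes, with ENSCAFG00000014207 among them (log2 fold change 0.70, adjusted p = 0.0492) and ENSCAFG00000014589 not (adjusted p = 0.406). The pseudo-F of the code was 0.720 (exact permutation test over 3003 splits, one-sided for larger values, p = 0.671; adjusted p = 0.806).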

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

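The checks for single libraries far from their group were run on 9 library measures and the 4 identifiers named for disease state, in both grades, which made 26 checks. Chance flags about 5% of such groups, and 2 were flagged, both in Moderate replicate 6. The 5 genes with the highest mean abundance over all libraries took 17.9% of its counts, against 7.28% to 11.5% in the other 9 Moderate libraries. Its position on the second principal component was 72.9, against -36.0 to 16.9 in the others. In this library the genes ranked 1, 2 and 5 by mean abundance took 7.98%, 5.72% and 3.17% of counts, each the highest value of all 14 libraries, while the gene ranked 4 took 0.0131%. Leaving it out gave 0 genes for Severe against Moderate and 2 genes for FS against the other codes (smallest adjusted p = 0.0492, edgeR's quasi-likelihood test). For Severe against Moderate, the count at an unadjusted p under 0.05 rose from 1111 to 1533 without it.

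The tests in this paragraph were chosen after the component had been seen. The first component, with 39.5% of the variance between libraries, was set against 5 explanations. Total counts shared 2.90% of the variance of the component, with an upper 95% limit of 41.3%, which argues against depth as the source of most of it. The share of counts taken by the 5 genes with the highest mean abundance shared 22.9% of it, with an upper 95% limit of 64.7%, so a few abundant genes stay open. The Moderate libraries alone covered 100% of the range of the component, and the code group with the smaller range covered 73.5% of it, so neither grade nor code can be the whole source. Libraries of the same breed entry lay 80.1 apart on average (6 pairs), against 65.6 with permuted breed labels (permutation test, one-sided for smaller gaps, p = 0.799), but 3 of these pairs are mixed dogs. The 3 pairs of a named breed lay 62.7 apart, against 65.5 with permuted labels (p = 0.467). These pairs lay from 8.84% to 58.3% of the range apart, and breed stays open, since 5 of the 9 breed entries have 1 library. The cell makeup of each sample, which needs marker genes, and the site sampled and RNA quality, for which no values were used here, stay open and untested.

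Whether chance can be excluded was examined with 100 splits of the 14 libraries into groups of the same sizes, the labelled split included. Those on adjusted counts and on the component were chosen after the result was seen. For both comparisons the labelled split called 0 genes, so that any split gives as many (100 of 100) and the adjusted counts decide nothing about chance. For disease state, 28 of 100 splits gave 1111 genes or more at an unadjusted p under 0.05, and the highest of the others gave 3623, so chance cannot be excluded. For the code, 74 of 100 gave 324 genes or more (highest other 3515), and chance cannot be excluded for that count either. A count over all genes cannot decide on chance for the few genes that some alternatives called. Of the 99 other splits for disease state, 1 called 282 genes, 1 called 6 and the rest called 0. For the code, 1 called 284 genes, 1 called 1 and the rest called 0. The 2 splits with the most calls had group means 77.8 and 77.9 apart on the first component, against 28.5 between the grades and 24.5 between the codes. For the code, the split with 284 calls also had the widest gap. The splits that called 6 genes for disease state and 1 gene for the code had gaps of 46.4 and 65.9, ranked 20 and 5 by gap. For disease state the widest gap, 82.7, gave 0 genes past the adjusted threshold but 3215 at an unadjusted p under 0.05. Over the 99 other splits the gap rose with the count at an unadjusted p under 0.05, at a Spearman's rho of 0.639 for disease state and 0.584 for the code, where splits share libraries and are not independent. This relation is partly built in, since the component is computed from the same genes. It therefore does not test whether splits with many genes follow the structure of the samples along this component, which stays a hypothesis.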

How the results depend on the processing

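The pseudo-F tests and breed as a covariate were chosen after the data were seen. For Severe against Moderate, all 27 alternatives called 0 genes. The minimum absolute log2 fold change of 1 only narrowed the 0 calls of the main test, so its result was fixed in advance. Over the others, the smallest adjusted p ranged from 0.0931 (DESeq2 Wald test) to 0.965 (edgeR without Severe replicate 2). The count at an unadjusted p under 0.05 fell from 1111 to 678, 604 and 733 without Severe replicates 2, 3 and 4. It rose to 1533 without Moderate replicate 6 and to 1422 without Moderate replicate 2. With limma-voom it was 2647, and with breed as a covariate, which left 4 residual degrees of freedom, it was 631. The cause of these shifts was not tested. The 4 identifiers named for disease state kept their direction in all 26 alternatives that gave a fold change, none past the threshold. They were picked by p from these same libraries and their grades did not overlap, so this agreement is no independent support. Upper-quartile factors put 48.5% of the genes at an unadjusted p under 0.05 lower in Severe, against 58.1% with TMM. The pseudo-F p ranged from 0.228 to 0.612 for disease state and from 0.310 to 0.956 for the code. For FS against the other codes, DESeq2's Wald test called 5 genes, and leaving out 1 library gave from 0 to 2 genes, the latter without Moderate replicate 6; the cause was not tested. The other 21 alternatives called 0, breed as a covariate among them. The minimum fold change could again give only 0. The count at an unadjusted p under 0.05 moved from 324 to 734 with no low-count filter, where more genes were tested. It was 631 with DESeq2, which was also run without that filter, and 526 without Moderate replicate 7. With the replicate block, on replicates 1 to 4 of both grades, edgeR called 0 genes (811 at an unadjusted p under 0.05), and 0 without the block on the same 8 libraries (1202). The replicate numbers showed no pairing: deviations of same-numbered libraries from their group means correlated at -0.38, 0.07, -0.12 and 0.02. No Severe library correlated best with the Moderate library of its own number. These correlations cannot decide it alone. By breed entry, Severe replicate 2 and Moderate replicate 3 were Cocker Spaniels. Moderate replicate 2 and Severe replicate 3 were Standard Poodles, which argues against pairing by dog for these numbers. The planned tests on 37 gene lists and 6 list-score relations, with their alternatives, were not run, because no identifier could be matched to a symbol. Depth was alike in all libraries (14565934 to 16421547 counts). In simulated data of the same size and depth, 70.6% of genes changed 4-fold and 29.4% of genes changed 2-fold between the grades were called.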

Other observations

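The tests in this part were chosen after the data were seen. Several of the most abundant genes of the gingiva varied widely between libraries of the same grade. The gene ranked 4 by mean abundance took 0.00700% of counts (1059 counts) in Moderate replicate 8 and 5.45% (854331 counts) in Moderate replicate 9, with 0.0275% to 0.876% in the 4 Severe libraries. The gene ranked 2 took 0.0552% in Moderate replicate 9 and 5.72% in Moderate replicate 6. By contrast, the gene ranked 3 stayed between 0.925% and 1.53% in all 14 libraries. Across the tested genes, 120 reached 10 CPM in at least 1 library and fell under 0.1 CPM in another.

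Of the tested genes, 928 correlated with the first component above 0.8 and 666 below -0.8 across the 14 libraries, 10.7% together, which is partly built in, since the component is computed from these genes. The 500 most variable genes alone gave a component that correlated with it at an absolute r of 0.989. Libraries high on it had more genes at 1 CPM or more, with Pearson's r = 0.756 and Spearman's rho = 0.710 over all libraries (r = 0.700 without Moderate replicates 8 and 1, the farthest from the median), and r = 0.798 and rho = 0.721 within the 10 Moderate libraries (r = 0.677 without the same 2). Both measures come from the same counts, although only the component used scaled totals and tested genes alone. This relation is therefore partly built in and no p-value is given for it. The p-values of the others were adjusted over a family of 6 relations, this one included. The relation with total counts was weak, at r = 0.170 (permutation p = 0.559, adjusted 0.559) and rho 0.187 (permutation p = 0.523, adjusted 0.523), with r = 0.0897 without Moderate replicate 3 and Severe replicate 2. Within Moderate these were r = 0.247 (permutation p = 0.492, adjusted 0.559) and rho 0.273 (permutation p = 0.446, adjusted 0.523), with r = 0.467 without Moderate replicates 3 and 5. The relation with the share of the 5 genes with the highest mean abundance was r = -0.478 (permutation p = 0.0778, adjusted 0.134) and rho -0.310 (permutation p = 0.281, adjusted 0.523), and fell to r = -0.185 without Moderate replicates 6 and 7, so it rested on those libraries. Within Moderate it was r = -0.550 (permutation p = 0.0892, adjusted 0.134) and rho -0.236 (permutation p = 0.517, adjusted 0.523), with r = -0.190 without the same 2.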
